A study of Mus musculus with 16 samples.

How the data were processed

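RNA was measured in 15 mouse mammary tumors and in 1 internal reference library, each sequenced as 1 library. Per the labels, the tumors grew from transplants of a Trp53 null mammary tumor family, called family F, in BALB/cJ females that were 8 to 10 weeks old. Mice entered treatment when a tumor measured 65 to 100 mm3, and the tumors were frozen 7 days after treatment. Each tumor is a separate mouse, so the 3 tumors of a group are biological replicates. RNA was extracted with a QIAGEN RNeasy kit, ribosomal RNA was depleted with QIAGEN FastSelect, and libraries were built with a NEBNext Ultra II kit, all per the labels.

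The deposited table holds a count of read fragments per gene and library, with no normalization, for 27179 Entrez genes on the mouse genome build GRCm38. The deposited annotation table adds other values, the exon coordinates and the summed exon length of each gene, in the same order of genes. Column names of the count table mention the Subread aligner. The aligner settings, the strand setting and the gene annotation release were not given in the sources used here. Gene symbols were joined to the Entrez identifiers through a mouse gene table, which matched 25275 of the 27179 identifiers. The share of counts on identifiers with no symbol was 7.86% to 13.8% of a tumor library, most of it on Entrez gene 100861531, a 5868 base model on chromosome 17 (39829210 to 39848825) that took 7.06% to 13.0% of the counts.

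Counts were analysed in R 4.3.3. Genes with low counts were removed by the default filter of edgeR 4.0.16 (filterByExpr on the 5 groups), which left 16017 genes, of which 15483 had a symbol. Libraries were scaled by TMM, with factors of 0.919 to 1.05, and edgeR quasi-likelihood models with 1 mean per group were fitted to all 15 tumors at once. The fit had 10 residual degrees of freedom, a common biological coefficient of variation of 0.364 and a median of 2.78 prior degrees of freedom. The 10 contrasts, listed with the results, and an F test for any difference among the 5 groups were tested, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Levels are given as CPM, the counts of a gene scaled to a common library total with the TMM factors, as mean ± SD over the 3 tumors of a group. Effects are log2 fold changes ± standard error, taken from the quasi-likelihood fit.

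Gene lists for 38 pathways and cell types (751 entries, of which 749 were found and 680 were tested) were tested by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment was over the 38 lists of a contrast. Counts of list members refer to the tested members, which the low-count filter kept, and not to the whole list. The same test was run with the correlation estimated per list, together with fry. For the members of each list, the number of genes passing the threshold over all genes tested was counted beside the number adjusted over the list alone. A list score of a tumor is the mean over the list of log2 CPM centred on each gene's mean. The comparisons, the lists, the tests and the alternatives were fixed before the data were examined, except for the alternatives and tests named as added.

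Genes to name were chosen by rule. For each contrast these were up to 6 genes with the largest changes in each direction among genes past the threshold with an average log2 CPM of at least 1 and, for 2 groups, no overlap between their tumors. The rule also took up to 4 members with the smallest unadjusted p of each list called by camera, and of 7 lists in any case: TGFb direct targets, Extracellular matrix and fibroblast activation, Type I interferon response, T cell markers, Cytotoxic lymphocyte effectors, p53 target genes and Alternative end joining. Trp53, Tgfbr1, Tgfb1 and Cd274 were always included. Genes named outside the rule are marked as chosen after their values were seen.

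Where a group had 0 counts of a gene in all 3 tumors, no fold change is given for it, and list medians are also given with such genes set to the bound that 3 counts over the group allow. These bounds cover counting error only. Total counts were 11002869 to 17184023 per tumor (median 13302488) and 9003730 in the reference library, and 17905 to 19896 genes had at least 1 count in a tumor. For pairs of tumors within a group, the chi-square per gene was 14.0 to 129 over genes with at least 20 counts in the pair, far above what counting error alone gives, and the Spearman correlation was 0.923 to 0.988, so no pair looked like a single tumor counted again.

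The pipeline was tested on simulated data drawn at the depth and spread of all 15 tumors, each gene independently of the others. Changes were placed in the TGFbi+RT group, in 5 runs with 100 changed genes of each size among 15770 to 15842 genes. It recovered a mean of 23% of the genes changed by 1 log2 unit and 71.2% of those changed by 2, with 5.8 false calls per run. In a contrast with no change it made 0.2 calls per run, and 0 other lists were called when 1 list was shifted. Because the genes were drawn independently, this cannot show list calls that arise from correlation between genes.

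Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no low-count filter, the replicate number as a block, the code in the library names as a covariate, the 2 resubmitted libraries left out, the 2 compared groups alone in the fit, and each of the 15 tumors left out in turn. Robust empirical Bayes, limma-voom with quality weights, the omission of 2 libraries that stood apart and the omission of Entrez gene 100861531 were added after the data were seen. The library code was A2301 for Sham, TGFbi, TGFbi+RT and replicate 1 of the triple group, and A2304 for RT and the other 2 triple tumors. The reference library belongs to no treatment group and entered no comparison between groups. Ratios of the tumors to it, given under the other observations, are mean log2 differences centred on the median gene.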

Results

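RNA was sequenced from 15 mouse mammary tumors of the Trp53 null transplant family F, 3 tumors in each of 5 treatment groups. The Sham group received control immunoglobulin. The TGFbi group received IPW-5371, a small molecule inhibitor of TGF beta signaling, at 20 mg/kg daily. The RT group received 10 Gy of focal radiation, the TGFbi+RT group received both, and the triple group, TGFbi+RT+anti-PD-L1, also received an antibody to the checkpoint ligand PD-L1 at 10 mg/kg weekly. Total counts per tumor ranged from 11002869 to 17184023, with a median of 13302488. The first principal component held 46.8% of the variance between tumors against 9.85% for the next. TGFbi+RT replicate 3 and triple replicate 2 stood apart on it, with scores of -102 and -114 against -33.1 to 88.5 in the other 13 tumors. In these 2 tumors Cxcl9, a chemokine induced by interferon gamma, reached 449 and 323 CPM against at most 7.59 CPM in any other tumor, and Gzmb, a protease of cytotoxic lymphocytes, reached 56.2 and 21.2 CPM against at most 1.41 CPM. Both genes were picked after their values were seen. Trp53 transcripts were present in every tumor at 63.9 to 110 CPM, with group means of 83.8 ± 3.58 CPM in Sham and 84.2 ± 7.41 CPM in TGFbi (SD, n = 3).

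TGFbi against Sham asked what the inhibitor did alone. Fbln7, which encodes a secreted adhesion protein of the fibulin family, fell from 21.9 ± 3.45 CPM in Sham to 3.86 ± 0.762 CPM in TGFbi (SD, n = 3), a log2 fold change of -2.50 ± 0.29 with an edgeR adjusted p of 0.0157. The call of Fbln7 in TGFbi vs Sham was not made by limma-voom (-2.49), with only the 2 groups in the fit (-2.48) or without the resubmitted libraries (-2.67). Nor was it made with the replicate number as a block. Fbln7 (Entrez 70370) lies on chromosome 2 from 128863932 to 128897034. Genes of bone morphogenetic protein signaling, a branch of the TGF beta superfamily, were lower as a list, with 13 of 15 members below Sham, a median log2 fold change of -0.96 and a camera adjusted p of 0.00208 (adjusted p = 0.971 with an estimated correlation). Within that list 2 genes were lower when adjusted over the list alone and 0 over all genes tested. The ligand Bmp4 measured 0.449 ± 0.221 CPM against 2.88 ± 1.37 CPM in Sham, and the Notch and BMP target Hey1 measured 9.72 ± 1.41 CPM against 22.5 ± 7.36 CPM (SD, n = 3). Markers of adipocytes were higher, with a median of 3.47 (camera adjusted p of 0.00143), and 7 of 14 members passed when adjusted over the list alone against 0 over all genes tested. With an estimated correlation the adjusted p was 0.971 for adipocyte markers, as it was for all lists of this comparison. The adipocyte rise was uneven, since Cfd, the adipokine adipsin, measured 80.8, 2.87 and 0.889 CPM in the 3 TGFbi tumors and 0 to 0.119 CPM in Sham. Myeloid and mast cell markers were also higher, with medians of 1.18 for monocytes and neutrophils (camera adjusted p of 0.00436), 1.52 for MHC class II (0.0113) and 3.32 for mast cells, eosinophils and basophils (0.00169), the last 2.65 with genes absent from Sham set to their bound. The adjusted p of these 3 lists was 0.971 with an estimated correlation. The hypoxia and glycolysis list was lower, with 22 of 23 members below Sham and a median of -0.49 (camera adjusted p of 0.00143, and adjusted p = 0.971 with an estimated correlation). BMP genes did not pass without Sham replicate 1 (-0.50), hypoxia genes without TGFbi replicate 1 (-0.40), or mast cell markers without TGFbi replicate 1 (2.77). MHC class II genes had 2.64 without Sham replicate 1 and did not pass without Sham replicate 2 (1.07), Sham replicate 3 (1.14), TGFbi replicate 1 (1.19) or TGFbi replicate 3 (1.09). Monocyte markers did not pass without Sham replicate 2 (0.89) or TGFbi replicate 1 (0.94), and had 0.78 without TGFbi replicate 3.

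Direct TGFb target genes did not pass as a list in the TGFbi tumors. Their median log2 fold change was -0.25, with 18 of 24 members below Sham (camera adjusted p of 0.330), and 0 members passed over all genes tested or adjusted over the list alone. Fstl3, a follistatin-like antagonist of activins, measured 1.32 ± 0.118 CPM against 3.39 ± 1.65 CPM in Sham, and Acta2, the smooth muscle actin of activated fibroblasts, measured 151 ± 37.4 CPM against 421 ± 192 CPM (SD, n = 3). The matrix and activated fibroblast list had a median of -0.44 (camera adjusted p of 0.480), a direction opposite to that of its test. Type I interferon genes (median 0.16, camera adjusted p of 0.276), T cell markers (0.71, 0.0925), cytotoxic effectors (2.55, or 2.08 with bounds, 0.241) and p53 targets (-0.10, 0.480) did not pass either. The T cell median was the log2 fold change of Bcl11b itself, a member with 786 counts over the Sham tumors where Cd3e had 1. Alternative end joining, an error-prone repair route, had a median of 0.07 (camera adjusted p of 0.397), while homologous recombination and Fanconi anemia genes were higher by a median of 0.13 (0.0417, and adjusted p = 0.971 with an estimated correlation). The homologous recombination median turned slightly negative without Sham replicate 1. Of the end joining genes, Rbbp8, the resection factor CtIP, measured 184 ± 73.9 CPM against 110 ± 15.5 CPM in Sham, an unadjusted p of 0.0087 and an adjusted p of 0.429 by edgeR. The remaining called lists were complement and coagulation (median 0.39, camera adjusted p of 0.0183), erythrocyte markers (1.07, 0.00436) and oxidative phosphorylation (-0.17, 0.0176). With an estimated correlation their adjusted p was 0.971. The mitochondrial share of counts was 3.03%, 3.70% and 6.45% in the 3 TGFbi tumors and 2.24% to 2.59% in Sham, and TGFbi replicate 3 held 6.30% of Rn7sk. Neither was tested as a source of these differences. The edgeR count of 1 gene compared with 1359 at an unadjusted p under 0.05, 116 by DESeq2 (39 higher and 77 lower) and 0 by limma-voom. Fbln7 alone made up the count, which was 0 without Sham replicate 2, TGFbi replicate 2 or TGFbi replicate 3, 2 without Sham replicate 1 and 5 without TGFbi replicate 1. The 10 called lists became 19 without Sham replicate 1 and 1 without TGFbi replicate 1, where Adipocyte markers in TGFbi vs Sham had a median of 1.24.

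RT against Sham asked what differed in irradiated tumors, all samples being labelled day 7. The smallest camera p was that of hypoxia and glycolysis genes, all 23 of which were below Sham, with a median log2 fold change of -0.89 and a camera adjusted p of 6.08e-23 (adjusted p = 0.508 with an estimated correlation). In this list 10 genes were lower when adjusted over the list alone and 0 over all genes tested. Slc2a1, the glucose transporter GLUT1, measured 78.6 ± 4.52 CPM against 202 ± 63.0 CPM in Sham. Egln3, an oxygen-sensing hydroxylase, measured 55.0 ± 14.2 CPM against 180 ± 17.6 CPM, and Ddit4, a stress inhibitor of mTOR, measured 90.0 ± 8.85 CPM against 176 ± 36.5 CPM (SD, n = 3). Luminal epithelial markers were higher by a median of 0.33 (camera adjusted p of 0.0325, and adjusted p = 0.947 with an estimated correlation), among them Elf5, a transcription factor of alveolar luminal cells, at 45.5 ± 6.83 CPM against 19.9 ± 9.69 CPM in Sham. Type I interferon genes were higher by a median of 0.80, with 27 of 28 members above Sham (camera adjusted p of 0.00136), and MHC class II genes by 1.54 (0.0248). Both had an adjusted p of 0.947 with an estimated correlation, and in both 0 genes passed over all genes tested or adjusted over the list alone. The type I interferon list did not pass without Sham replicate 2 (0.41) or RT replicate 1 (0.24). MHC class II genes had 2.45 without Sham replicate 1 and did not pass without Sham replicate 2 (1.00), Sham replicate 3 (0.95) or RT replicate 1 (0.69). Luminal markers had 1.06 without Sham replicate 1 and did not pass without Sham replicate 2 (0.00) or RT replicate 2 (0.35). Oxidative phosphorylation had -0.24 without Sham replicate 1 and did not pass without Sham replicate 2 (-0.01), Sham replicate 3 (-0.17) or RT replicate 1 (-0.06).

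The p53 targets did not pass as a list after radiation, with a median of -0.06 and 10 of 24 members above Sham (camera adjusted p of 0.824). Cdkn1a, the cell cycle inhibitor p21, measured 21.6 ± 11.5 CPM against 22.9 ± 14.3 CPM in Sham (SD, n = 3). Alternative end joining genes (median -0.02, camera adjusted p of 0.858), TGFb targets (-0.21, 0.220), matrix genes (0.11, 0.517), T cell markers (1.18, or 1.02 with bounds, 0.0863) and cytotoxic effectors (2.37, or 1.48 with bounds, 0.401) did not pass as lists. Oxidative phosphorylation genes were lower by a median of -0.13 (camera adjusted p of 0.0325, and adjusted p = 0.947 with an estimated correlation). By edgeR 0 genes passed, with 672 at an unadjusted p under 0.05 where chance would give 801. DESeq2 called 1 gene, limma-voom 0, and edgeR 1 without triple replicate 3. All RT libraries carried code A2304 and all Sham libraries A2301, so no value within a code exists, and a fit with the code as a term, which rests on the triple group, gave medians of -1.66 for Type I interferon response in RT vs Sham, -0.95 for MHC class II antigen presentation in RT vs Sham and -1.72 for Hypoxia and glycolysis in RT vs Sham. The 5 called lists became 17, 3, 8, 10, 9, 14 and 9 without Sham replicate 1, Sham replicate 3, TGFbi+RT replicate 3, RT replicate 1, RT replicate 2, RT replicate 3 and triple replicate 2, in that order.

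TGFbi+RT against Sham asked what the inhibitor and radiation did together. Interferon-stimulated genes were higher across the list, with 28 of 28 type I interferon response genes above Sham, a median log2 fold change of 2.97 and a camera adjusted p of 2.14e-14 (adjusted p = 0.632 with an estimated correlation). Adjusted over the list alone 24 of the 28 genes were higher, against 0 over all genes tested and 15 by DESeq2. Oas2, an antiviral RNA sensor, measured 35.0 ± 30.3 CPM against 1.42 ± 1.27 CPM in Sham, and Trim30a, an interferon-induced ubiquitin ligase, measured 48.2 ± 50.9 CPM against 2.85 ± 2.14 CPM (SD, n = 3). MHC class II genes, which present antigen to helper T cells, were higher by a median of 4.67, and 9 of 9 passed when adjusted over the list alone (camera adjusted p of 2.99e-07, and adjusted p = 0.632 with an estimated correlation). H2-Aa measured 67.4 ± 79.8 CPM against 1.77 ± 1.17 CPM in Sham. T cell markers were higher by a median of 3.44, or 3.10 with bounds (camera adjusted p of 1.52e-06, and adjusted p = 0.673 with an estimated correlation), and 11 of 21 passed when adjusted over the list alone. Cytotoxic effectors were higher by 7.41, or 6.68 with bounds (camera adjusted p of 1.25e-06, and adjusted p = 0.632 with an estimated correlation). Of 20 listed effectors 10 were tested, and 9 of these passed when adjusted over the list alone. The granzyme Gzmb measured 19.6 ± 31.7 CPM and the natural killer receptor Ncr1 6.88 ± 9.99 CPM in TGFbi+RT, and both had 0 counts in all 3 Sham tumors. Without TGFbi+RT replicate 3 all of these lists passed, with medians of 4.64 for Cytotoxic lymphocyte effectors in TGFbi+RT vs Sham, 1.80 for T cell markers in TGFbi+RT vs Sham, 1.49 for Type I interferon response in TGFbi+RT vs Sham and 2.62 for MHC class II antigen presentation in TGFbi+RT vs Sham. Perforin, Prf1, measured 18.2 ± 29.1 CPM against 0.156 ± 0.0872 CPM in Sham (SD, n = 3).

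**Figure D1:**
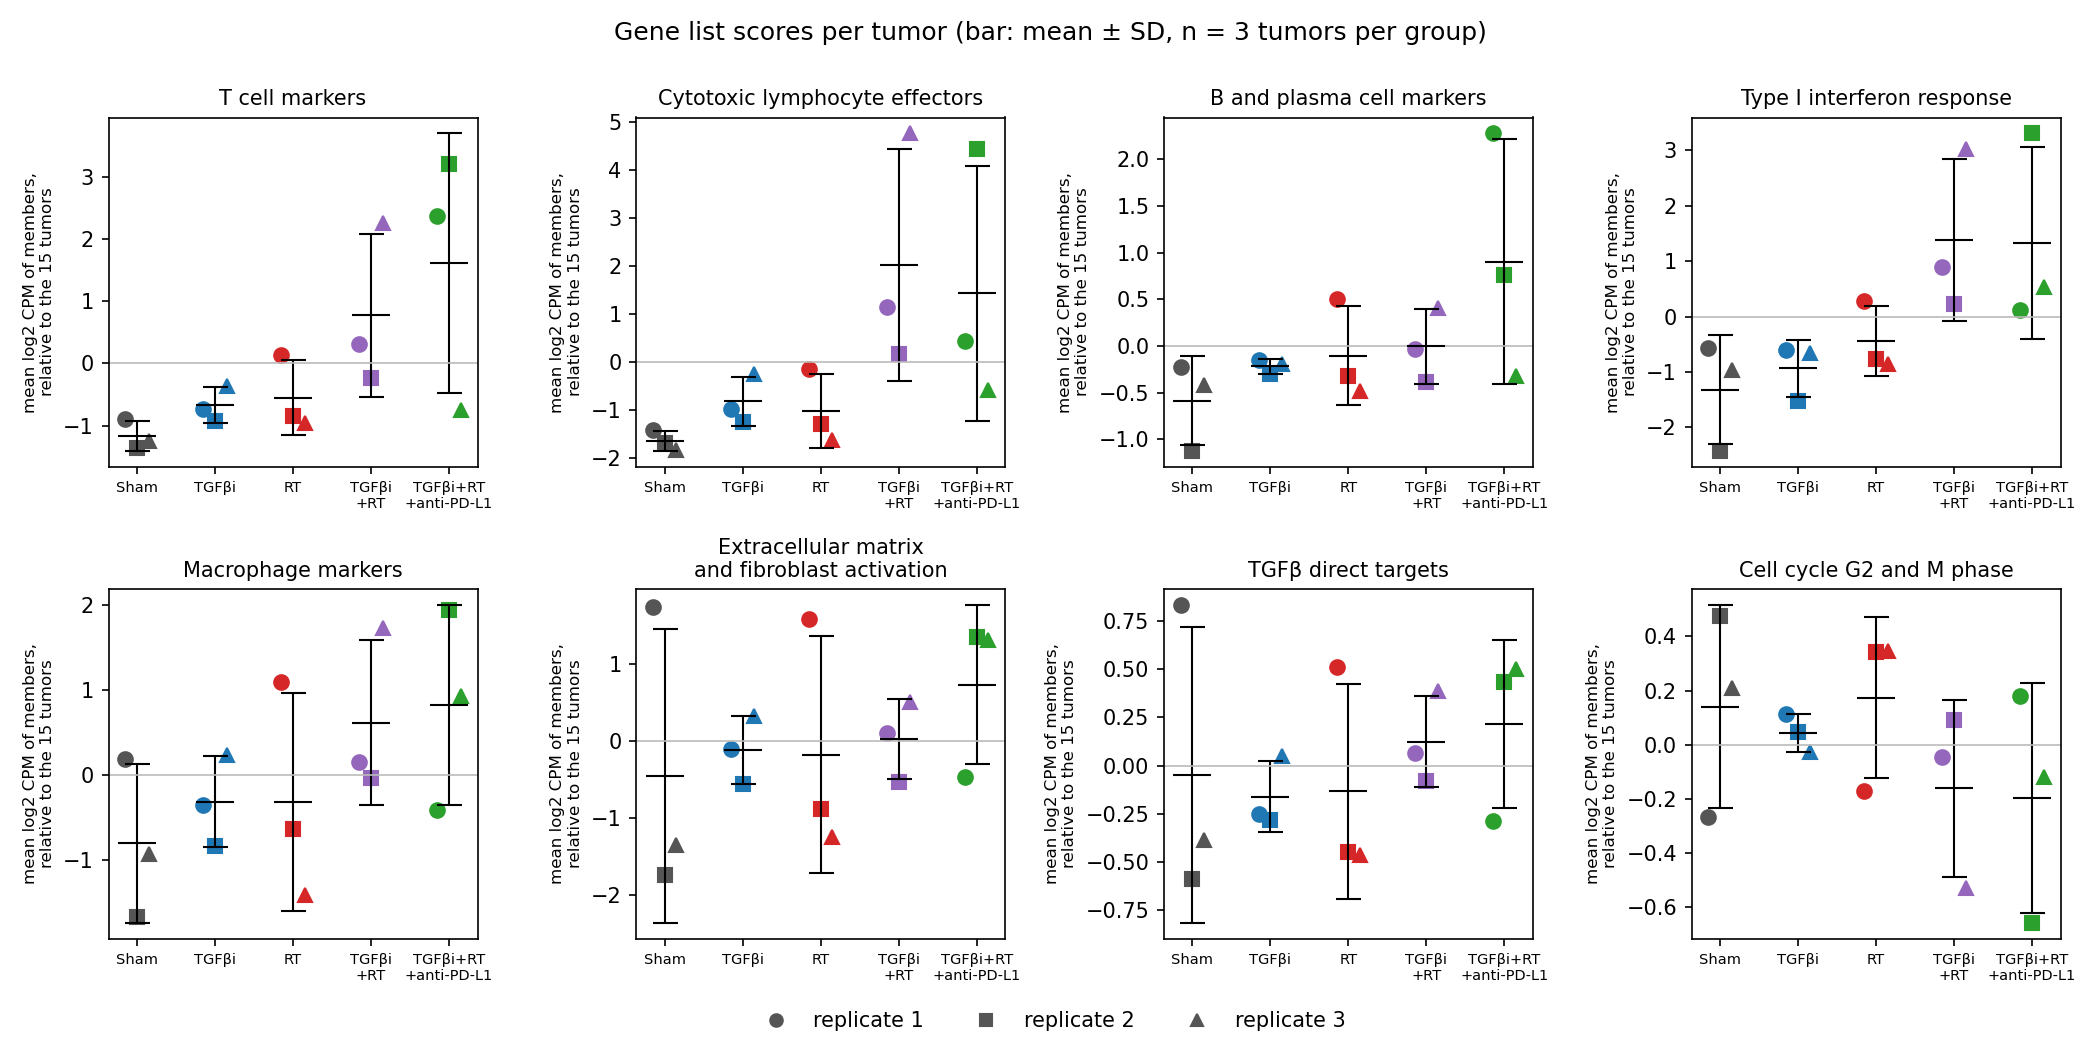
Scores of 8 gene lists in each tumor, by treatment group (mean log2 CPM of the list, centred over the 15 tumors), with points for tumors and bars for the group mean ± SD (n = 3). TGFbi+RT replicate 3 and triple replicate 2 have the highest type I interferon scores, 3.01 and 3.30, and Sham has the lowest group mean, -1.32.

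Other leukocyte groups moved the same way in TGFbi+RT. Monocyte and neutrophil markers had a median of 2.17 (camera adjusted p of 4.18e-07), dendritic cell markers 2.65 (3.82e-06) and mast cell, eosinophil and basophil markers 4.27, or 3.71 with bounds (7.10e-06). Each of these 3 lists had an adjusted p of 0.632 with an estimated correlation. Ccl8, a chemokine that attracts monocytes, measured 166 ± 191 CPM against 3.99 ± 2.57 CPM in Sham, and Ccl22, a dendritic cell chemokine, measured 11.4 ± 14.7 CPM against 0.192 ± 0.108 CPM (SD, n = 3). Macrophage markers (median 1.47, camera adjusted p of 2.67e-05), regulatory T cell and checkpoint genes (1.44, 0.00123), interferon gamma and MHC class I genes (2.57, 5.00e-07) and adipocyte markers (3.95, 0.000396) were higher too. These 4 lists had an adjusted p of 0.685 with an estimated correlation. The adipocyte members were not uniform. Thrsp had a log2 fold change of -1.21 ± 0.36, while Cfd, with 3 counts over the Sham tumors, had 8.73 ± 2.48. Cd274, the gene of PD-L1, measured 184.6, 11.2 and 10.2 CPM in TGFbi+RT replicates 3, 1 and 2 and 2.62 to 7.52 CPM in Sham. Cell cycle genes were slightly lower, with 24 of 24 G2 and M phase genes below Sham and a median of -0.33 (camera adjusted p of 0.000876, and adjusted p = 0.814 with an estimated correlation), and 23 of 24 S phase genes with a median of -0.29 (0.0120, and adjusted p = 0.831 with an estimated correlation). Neither cell cycle list passed without TGFbi+RT replicate 3, with medians of -0.17 for G2 and M phase and -0.14 for S phase, or without Sham replicate 2, with -0.15 and -0.11, and S phase did not pass without Sham replicate 3 (-0.21). Without Sham replicate 1 they had -0.54 and -0.49. Lists that passed without TGFbi+RT replicate 3 with smaller medians were interferon gamma and MHC class I genes (0.71), macrophage markers (0.61), regulatory T cell and checkpoint genes (0.83), dendritic cell markers (1.33) and adipocyte markers (2.60). Quiescent fibroblast markers had 1.99 without Sham replicate 1 and did not pass without Sham replicate 2 (0.37), Sham replicate 3 (0.23) or TGFbi+RT replicate 3 (0.47). TGFb targets (median -0.17, camera adjusted p of 0.975), matrix genes (-0.28, 0.400), p53 targets (0.12, 0.502) and alternative end joining (-0.11, 0.244) did not pass, and for TGFb targets and matrix genes the test pointed up. The gene Tgfbi, a matrix protein named for its induction by TGF beta, measured 43.4 ± 23.0 CPM against 9.61 ± 6.61 CPM in Sham, with an edgeR adjusted p of 0.211.

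Of the 18 lists called in TGFbi+RT against Sham, the rest were inflammatory chemokines (median 1.68, camera adjusted p of 6.63e-07, and adjusted p = 0.655 with an estimated correlation), complement and coagulation (1.43, 1.52e-05, and adjusted p = 0.685 with an estimated correlation), quiescent fibroblasts (0.58, 0.0137, and adjusted p = 0.765 with an estimated correlation), hypoxia and glycolysis (-0.34, 0.0120, and adjusted p = 0.814 with an estimated correlation) and oxidative phosphorylation (-0.30, 9.11e-05, and adjusted p = 0.655 with an estimated correlation). Over all genes edgeR called 0, with 2409 at an unadjusted p under 0.05 and a smallest adjusted p of 0.207, where DESeq2 called 481 (379 higher and 102 lower) and limma-voom 0. The 6 libraries shared code A2301. Without TGFbi+RT replicate 3 and triple replicate 2, an omission added after the data were seen, 15 lists were called.

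TGFbi+RT+anti-PD-L1 against Sham asked what all 3 agents did. T cell markers were higher by a median of 5.04, or 4.80 with bounds, and 17 of 21 passed when adjusted over the list alone, 0 over all genes tested and 14 by DESeq2 (camera adjusted p of 2.33e-10, and adjusted p = 0.397 with an estimated correlation). Trac, the constant region of the T cell receptor alpha chain, measured 8.05 ± 7.26 CPM against 0.318 ± 0.241 CPM in Sham, and Cd8a, the coreceptor of cytotoxic T cells, 6.78 ± 6.55 CPM against 0.0688 ± 0.0116 CPM (SD, n = 3). The T cells were unevenly spread, with Cd3e at 9.20, 22.3 and 0.253 CPM in triple replicates 1, 2 and 3. Type I interferon genes were higher by 3.06 (camera adjusted p of 3.88e-14) with 26 of 28 passing when adjusted over the list alone, MHC class II genes by 5.22 (7.74e-09) with 9 of 9, and cytotoxic effectors by 7.13, or 6.29 with bounds (1.78e-05), with 10 of 10. Each of these 3 lists had an adjusted p of 0.397 with an estimated correlation. Without triple replicate 2 they passed with medians of 1.35 for type I interferon, 2.74 for MHC class II and 3.12 for cytotoxic effectors. Without both libraries that stood apart T cell markers passed with 2.64. That omission left triple replicates 1 and 3, and of these only replicate 1 had high Cd3e. Lymph node genes were also high in triple replicate 1, so the 2.64 is not free of lymph node tissue as a possible source. B and plasma cell markers were higher by 1.95 (camera adjusted p of 0.0215, and adjusted p = 0.397 with an estimated correlation), and Ighm, the heavy chain of immunoglobulin M, measured 40.8 ± 29.8 CPM against 0.725 ± 0.509 CPM in Sham (SD, n = 3). Complement genes were higher by 2.01, and by 3.39 without Sham replicate 1 (camera adjusted p of 9.50e-09, and adjusted p = 0.397 with an estimated correlation), with C3, the central complement protein, at 611 ± 700 CPM against 14.3 ± 17.9 CPM. Hypoxia and glycolysis genes were lower in all 23 members by a median of -0.74, or -1.31 without triple replicate 3 (camera adjusted p of 2.79e-11, and adjusted p = 0.397 with an estimated correlation).

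Stromal lists also passed in the triple group. Matrix and activated fibroblast genes were higher by a median of 0.47 (camera adjusted p of 0.00149, and adjusted p = 0.601 with an estimated correlation), and Lum, a collagen-binding proteoglycan, measured 46.1 ± 40.4 CPM against 5.44 ± 7.54 CPM in Sham. Quiescent fibroblast markers were higher by 1.35 (camera adjusted p of 1.26e-05, and adjusted p = 0.397 with an estimated correlation) and immediate early genes by 0.61 (0.000908, and adjusted p = 0.432 with an estimated correlation). The matrix list had 2.25, 0.84 and 0.28 without Sham replicate 1, triple replicate 1 and triple replicate 2, and did not pass without Sham replicate 2 (0.09), Sham replicate 3 (0.08) or triple replicate 3 (0.21). Immediate early genes had 1.45, 0.36 and 0.15 without Sham replicate 1, Sham replicate 3 and triple replicate 2, and quiescent fibroblast markers 2.42 without Sham replicate 1. TGFb targets had a median of 0.00 (camera adjusted p of 0.722), p53 targets 0.26 (0.106) and alternative end joining -0.12 (0.0979), and none of these passed. In all 26 lists were called, 21 higher and 5 lower, and the 2 libraries that stood apart left 21 when omitted. Over all genes edgeR called 0, with 2385 at an unadjusted p under 0.05 and a smallest adjusted p of 0.194, where DESeq2 called 619 (517 higher and 102 lower), limma-voom 0, and edgeR 4 without triple replicate 3. Without triple replicate 1, B and plasma cell markers in TGFbi+RT+anti-PD-L1 vs Sham had a median of 0.41 and did not pass. Triple replicate 1 alone shared code A2301 with Sham, and with the code in the fit 17 lists were called and the median of Extracellular matrix and fibroblast activation in TGFbi+RT+anti-PD-L1 vs Sham was -0.96.

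TGFbi+RT against RT asked what the inhibitor added to radiation. Interferon gamma and MHC class I genes were higher in 27 of 27 members, with a median of 2.36 and 13 passing when adjusted over the list alone (camera adjusted p of 7.96e-08, and adjusted p = 0.554 with an estimated correlation). Higher too were type I interferon genes by 2.16 (camera adjusted p of 8.85e-10), cytotoxic effectors by 4.97 with 7 of 10 passing when adjusted over the list alone (3.45e-06), and MHC class II genes by 3.06 with 6 of 9 (2.73e-05). Each of these 3 lists had an adjusted p of 0.554 with an estimated correlation. T cell markers were higher by 2.03 (camera adjusted p of 0.000193, and adjusted p = 0.555 with an estimated correlation). Hypoxia and glycolysis genes were higher in 22 of 23 members, by a median of 0.55 (camera adjusted p of 2.38e-06, and adjusted p = 0.554 with an estimated correlation), led by Car9, a carbonic anhydrase induced by hypoxia, at 7.54 ± 2.18 CPM against 1.53 ± 0.731 CPM in RT (SD, n = 3). Car9 had an edgeR adjusted p of 0.414. Cell cycle genes were lower, with 24 of 24 members of both the S phase list (median -0.33, camera adjusted p of 0.000255) and the G2 and M phase list (-0.33, 8.37e-05) below RT. Both had an adjusted p of 0.623 with an estimated correlation. Without TGFbi+RT replicate 3 the S phase list passed with -0.17 and the G2 and M phase list, at -0.18, did not, while interferon gamma and MHC class I genes passed with 0.39 and MHC class II genes with 1.30. Hypoxia genes passed with 0.31 without TGFbi+RT replicate 2. TGFb targets (median 0.07, camera adjusted p of 0.203), matrix genes (-0.34, 0.741, its test pointing up), p53 targets (0.12, 0.330) and alternative end joining (-0.07, 0.203) did not pass.

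In TGFbi+RT against RT 22 lists were called, 19 higher and 3 lower, and 17 without the 2 libraries that stood apart, where T cell markers in TGFbi+RT vs RT had a median of 0.34 and did not pass. Without TGFbi+RT replicate 3 alone that median was 0.63 and did not pass, while Cytotoxic lymphocyte effectors in TGFbi+RT vs RT passed with 2.31 and Type I interferon response in TGFbi+RT vs RT with 0.92. Over all genes edgeR called 0, with 1541 at an unadjusted p under 0.05, 63 by DESeq2 (47 higher and 16 lower) and 0 by limma-voom. The codes of the libraries separate these groups completely, and with the code in the fit T cell markers in TGFbi+RT vs RT had a median of 2.06, but the test pointed down and did not pass.

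TGFbi+RT against TGFbi asked what radiation added to the inhibitor. The smallest camera p was that of type I interferon genes, higher in 28 of 28 members, with a median of 2.75 and 27 passing when adjusted over the list alone, 0 over all genes tested and 0 by DESeq2 (camera adjusted p of 3.44e-19, and adjusted p = 0.481 with an estimated correlation). Oas3, an antiviral synthetase, measured 32.8 ± 32.1 CPM against 2.17 ± 1.21 CPM in TGFbi, and Cxcl10, a chemokine that attracts T cells, 71.0 ± 113 CPM against 2.27 ± 0.525 CPM (SD, n = 3). Interferon gamma and MHC class I genes were higher by 2.58 with 17 of 27 passing when adjusted over the list alone (camera adjusted p of 8.94e-12), and cytotoxic effectors by 5.18 with 8 of 10 (6.94e-07). Both had an adjusted p of 0.481 with an estimated correlation. Without TGFbi+RT replicate 3 these 3 lists passed, with medians of 1.36 for Type I interferon response in TGFbi+RT vs TGFbi, 0.59 for Interferon gamma response and antigen presentation by MHC class I in TGFbi+RT vs TGFbi and 1.88 for Cytotoxic lymphocyte effectors in TGFbi+RT vs TGFbi. T cell markers were higher by 2.63 with or without bounds (camera adjusted p of 5.86e-05, and adjusted p = 0.517 with an estimated correlation), by 0.80 without TGFbi+RT replicate 3, and at 0.57 did not pass without both libraries that stood apart. Luminal markers were higher by 0.60 (camera adjusted p of 0.00234, and adjusted p = 0.553 with an estimated correlation) and basal and keratinocyte markers lower by a median of -0.55 (0.00696, and adjusted p = 0.481 with an estimated correlation). Luminal markers had 2.08 and 0.34 without TGFbi replicates 1 and 3 and did not pass without TGFbi+RT replicate 3 (-0.06) or TGFbi replicate 2 (0.15), and basal markers did not pass without TGFbi+RT replicate 3 (-0.30) or TGFbi replicate 1 (-0.15). Krt5, a basal keratin, measured 541 ± 201 CPM against 902 ± 261 CPM in TGFbi (SD, n = 3).

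Of 3 DNA repair lists, 2 were lower when radiation was added to the inhibitor, and classical non-homologous end joining did not pass (median 0.01, its test pointing down, camera adjusted p of 0.682). Alternative end joining had a median of -0.17 with 16 of 18 members lower (camera adjusted p of 0.00226, and adjusted p = 0.481 with an estimated correlation). Homologous recombination and Fanconi anemia genes had a median of -0.17 with 20 of 24 lower (camera adjusted p of 0.00132, and adjusted p = 0.533 with an estimated correlation). Rbbp8 measured 107 ± 17.9 CPM against 184 ± 73.9 CPM in TGFbi, and Lig1, the replicative DNA ligase, 56.8 ± 5.50 CPM against 76.0 ± 9.49 CPM (SD, n = 3). S phase genes were lower by a median of -0.29 (camera adjusted p of 5.64e-06, and adjusted p = 0.517 with an estimated correlation) and p53 targets higher by 0.20 (0.0432, and adjusted p = 0.517 with an estimated correlation), with Cdkn1a at 55.2 ± 34.9 CPM against 24.0 ± 9.88 CPM in TGFbi. The p53 call ended in 13 of 15 omissions of a single tumor, with medians from 0.10 to 0.30. Alternative end joining passed with -0.09 without TGFbi+RT replicate 3 and -0.08 without TGFbi replicate 2, and homologous recombination with -0.35 without TGFbi+RT replicate 2, but alternative end joining did not pass without both libraries that stood apart (-0.08). TGFb targets (median 0.31, camera adjusted p of 0.152) and matrix genes (0.19, 0.770) did not pass. Of 25 called lists, 18 higher and 7 lower, 15 remained in number without TGFbi+RT replicate 3 and 11 without both libraries that stood apart. Over all genes edgeR called 0, with 970 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom, and all 6 libraries shared code A2301.

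TGFbi+RT+anti-PD-L1 against TGFbi+RT asked what checkpoint blockade added. Matrix and activated fibroblast genes were higher in 28 of 29 members, with a median of 0.77 (camera adjusted p of 0.00325). B and plasma cell markers were higher in 9 of the 9 members tested out of 18 listed, with a median of 1.60 (camera adjusted p of 0.00356). T cell markers were higher by a median of 0.98 (camera adjusted p of 0.00507), pericyte markers by 0.51 (0.00325) and endothelial markers by 0.41 (0.00958). The adjusted p of these 5 lists was 0.935 with an estimated correlation. Igkc, the immunoglobulin kappa chain, measured 9.65 ± 13.9 CPM against 0.483 ± 0.268 CPM in TGFbi+RT, and Cd8a 6.78 ± 6.55 CPM against 0.836 ± 1.13 CPM (SD, n = 3). Hypoxia and glycolysis genes were lower by a median of -0.44 (camera adjusted p of 1.60e-11, and adjusted p = 0.935 with an estimated correlation), with Car9 at 2.86 ± 1.41 CPM against 7.54 ± 2.18 CPM in TGFbi+RT. The hypoxia score ran from -1.17 to 0.59 in the triple group around a mean of -0.41, against a mean of 0.24 in TGFbi+RT, and the median passed with -0.19, -0.91 and -0.24 without triple replicate 2, triple replicate 3 and TGFbi+RT replicate 2. Type I interferon genes (median 0.20, camera adjusted p of 0.870), cytotoxic effectors (-0.34, 0.262), TGFb targets (0.12, 0.789), p53 targets (0.18, 0.361) and alternative end joining (0.00, 0.785) did not pass. The type I interferon median was opposite in sign to its test. In B and plasma cell markers 2 genes passed when adjusted over the list alone, and 0 passed in the other 4 higher lists or over all genes tested.

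Calls made for anti-PD-L1 changed when single libraries were left out. Without triple replicate 1, B and plasma cell markers in TGFbi+RT+anti-PD-L1 vs TGFbi+RT had a median of 0.31 and did not pass. Igkc measured 25.5 CPM in that tumor against 3.34 and 0.0844 CPM in triple replicates 2 and 3. Lymph node genes were high in it as well, such as Glycam1 with 420 counts against 0 and 1 in the libraries that stood apart. Lymph node tissue stays open as a source of the T and B cell markers of triple replicate 1. Without triple replicate 2 the median of T cell markers in TGFbi+RT+anti-PD-L1 vs TGFbi+RT was 0.02. T cell markers also failed to pass without TGFbi+RT replicate 1 (0.68), TGFbi+RT replicate 2 (0.52) or triple replicate 1 (1.06), and had 2.77 without TGFbi+RT replicate 3 and 1.56 without triple replicate 3. Matrix genes did not pass without TGFbi+RT replicate 2 (0.62), triple replicate 2 (0.56) or triple replicate 3 (0.61), and had 1.31 without TGFbi+RT replicate 3 and 1.20 without triple replicate 1. The 13 called lists, 9 higher and 4 lower, became 6 without TGFbi+RT replicate 2, 23 without TGFbi+RT replicate 3 and 11 without the 2 libraries that stood apart. Over all genes edgeR called 0, with 318 at an unadjusted p under 0.05 where chance would give 801, 1 by DESeq2 and 0 by limma-voom. Only triple replicate 1 shared code A2301 with TGFbi+RT, and with the code in the fit Extracellular matrix and fibroblast activation in TGFbi+RT+anti-PD-L1 vs TGFbi+RT had a median of -0.61. The median of endothelial markers turned negative with the code as well.

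The interaction of TGFbi and RT asked whether radiation acted differently when the inhibitor was present. Hypoxia and glycolysis genes had the smallest camera p, with 23 of 23 members positive, a median of 1.00 and a camera adjusted p of 1.30e-13 (adjusted p = 0.799 with an estimated correlation). The group means of this list's score were 0.57 in Sham, 0.10 in TGFbi, -0.49 in RT and 0.24 in TGFbi+RT. In it 2 genes passed when adjusted over the list alone. All RT libraries carried code A2304, and all Sham, TGFbi and TGFbi+RT libraries A2301. Within these groups the interaction of any list therefore cannot be told apart from the code. The interaction of type I interferon genes had a median of 1.97 (camera adjusted p of 6.74e-06), cytotoxic effectors 1.89 (0.00224) and alternative end joining -0.07 (0.0378). The adjusted p of these 3 lists was 0.799 with an estimated correlation. TGFb targets had a median of 0.29 (camera adjusted p of 0.0378, and adjusted p = 0.867 with an estimated correlation), with Bhlhe40, a transcription factor induced by both TGF beta and hypoxia, at 272 ± 34.9 CPM in Sham, 161 ± 11.0 CPM in TGFbi, 136 ± 8.34 CPM in RT and 196 ± 56.7 CPM in TGFbi+RT (SD, n = 3). Bhlhe40 was the member of this list that passed when adjusted over the list alone. T cell markers (median 0.57, camera adjusted p of 0.153), matrix genes (0.20, 0.758, its test in the opposite direction) and p53 targets (0.14, 0.126) did not pass. Type I interferon genes (0.77), cytotoxic effectors (-0.33), alternative end joining (-0.12) and TGFb targets (0.22) did not pass without TGFbi+RT replicate 3. The median of TGFb targets turned slightly negative without Sham replicate 1. Over all genes edgeR called 0, with 608 at an unadjusted p under 0.05 where chance would give 801, 3 by DESeq2 and 0 by limma-voom. The 15 called lists became 1 without TGFbi+RT replicate 3, 5 without both libraries that stood apart, 8 without Sham replicate 1, 9 without TGFbi+RT replicate 1, 9 without TGFbi replicate 2, 24 without RT replicate 1 and 8 without RT replicate 2.

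The average effect of RT was taken over tumors with and without the inhibitor, 6 against 6. Type I interferon genes were higher in 28 of 28 members by a median of 1.84 (camera adjusted p of 8.81e-18, and adjusted p = 0.630 with an estimated correlation), with 23 passing when adjusted over the list alone. Among immune and epithelial lists, T cell markers were higher by 2.59 (camera adjusted p of 1.83e-05), cytotoxic effectors by 3.86 (1.78e-05) and luminal markers by 0.41 (0.000152), while hypoxia and glycolysis genes were lower by a median of -0.43 (1.98e-09), basal and keratinocyte markers by -0.44 (0.00814) and alternative end joining by -0.08 (0.0294). Each of these 6 lists had an adjusted p of 0.630 with an estimated correlation. The medians that passed without TGFbi+RT replicate 3 were 1.09 for type I interferon, 1.46 for T cell markers, 2.43 for cytotoxic effectors and 0.26 for luminal markers, while basal markers (-0.32) and alternative end joining (-0.08) did not. Without RT replicate 1 T cell markers had 1.54 and cytotoxic effectors 2.28. Krt5 passed in the basal list when adjusted over the list alone, with a log2 fold change of -0.76 ± 0.18. TGFb targets (median -0.01, camera adjusted p of 0.915), matrix genes (0.10, 0.481) and p53 targets (0.11, 0.270) did not pass. In all 21 lists were called, 13 higher and 8 lower, and 0 genes by edgeR, with 980 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom. With the library code in the fit, Macrophage markers in average effect of RT had a median of -0.15 and Cell cycle S phase in average effect of RT of 0.17, both opposite to the values without it. The median of alternative end joining turned positive with the code as well.

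The average effect of TGFbi was taken over tumors with and without radiation, 6 against 6, and here 5 genes passed by edgeR. Duox1, a dual oxidase that makes hydrogen peroxide, rose by a log2 fold change of 1.72 ± 0.22 (adjusted p of 0.0216), from 7.68 ± 2.45 CPM in Sham and 7.53 ± 1.39 CPM in RT to 27.4 ± 4.51 CPM in TGFbi and 22.9 ± 9.06 CPM in TGFbi+RT (SD, n = 3). Crabp1, a retinoic acid binding protein, rose by 1.95 ± 0.29 (adjusted p of 0.0461). Fbln7 fell by a log2 fold change of -1.58 ± 0.20 and Ndp, the Wnt receptor ligand norrin, by -1.55 ± 0.20 (both with an adjusted p of 0.0216). Ext2, a glycosyltransferase that builds heparan sulfate, fell by a log2 fold change of -0.57 ± 0.08 (adjusted p of 0.0357), from 112 ± 3.31 CPM in Sham to 76.6 ± 7.46 CPM in TGFbi and from 111 ± 6.09 CPM in RT to 73.6 ± 3.14 CPM in TGFbi+RT (SD, n = 3). Duox1 (Entrez 99439) lies on chromosome 2 from 122315672 to 122347972, Crabp1 (Entrez 12903) on chromosome 9 from 54764808 to 54773109, Ndp (Entrez 17986) on chromosome X from 16885521 to 16911764 and Ext2 (Entrez 14043) on chromosome 2 from 93695631 to 93822568. The triple group also received the inhibitor but was outside this contrast. Its counts over 3 tumors, not scaled to depth, were 708 for Crabp1 (710 in Sham and 2982 in TGFbi) and 733 for Fbln7 (961 and 140). They were 80 for Ndp (86 and 29), 575 for Duox1 (344 and 988) and 3736 for Ext2 (4994 and 2779). DESeq2 called 468 genes (276 higher and 192 lower), limma-voom 2 (Duox1 and Fbln7), and 2297 genes had an unadjusted p under 0.05 by edgeR. The mitochondrial share of counts was 2.89% to 6.45% in the 6 inhibitor tumors and 2.24% to 3.07% in the other 6, and TGFbi replicate 3 held 6.30% of Rn7sk against a median of 1.87%, and neither was tested as a source of these changes. The count of 5 became 0 with the library code in the fit and 0 without Sham replicate 2, Sham replicate 3, TGFbi replicate 2, TGFbi+RT replicate 3, RT replicate 2 or RT replicate 3, although every one of these fits gave the 5 genes the same direction. It became 2 without TGFbi+RT replicate 2, TGFbi replicate 3 or the 2 libraries that stood apart, and 8 without TGFbi replicate 1.

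**Figure D2:**
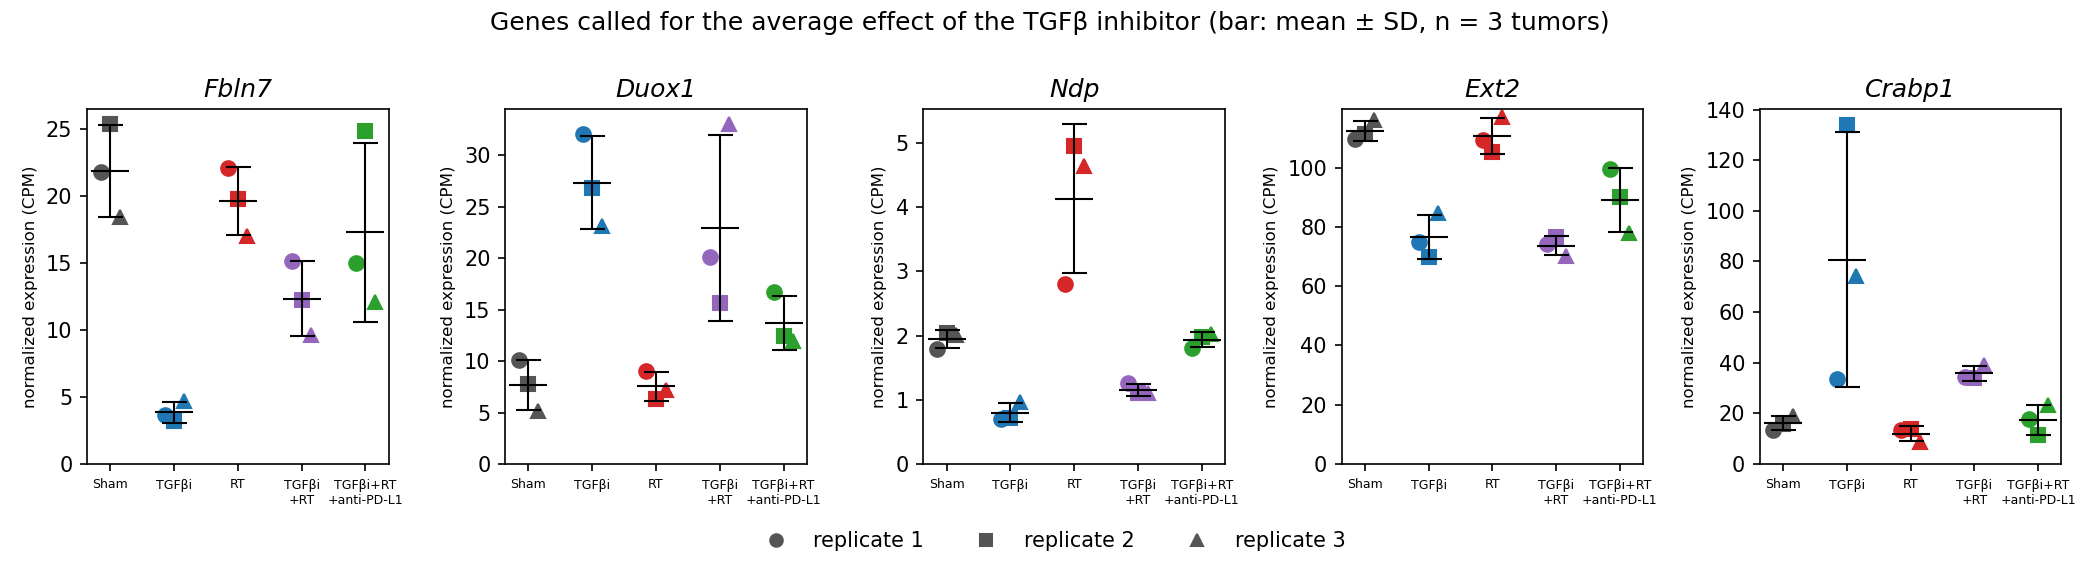
Levels in CPM of Fbln7, Duox1, Ndp, Ext2 and Crabp1 in each tumor, by treatment group, with points for tumors and bars for the group mean ± SD (n = 3). Duox1 averages 27.4 CPM in TGFbi and 22.9 CPM in TGFbi+RT against 7.68 CPM in Sham and 7.53 CPM in RT, and Ext2 averages 76.6 and 73.6 CPM against 112 and 111 CPM. The triple group, which also received the inhibitor, had 708 unscaled counts of Crabp1 over its tumors, against 710 in Sham and 2982 in TGFbi.

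Of the lists, 19 were called for the average effect of TGFbi, 16 higher and 3 lower. Adipocyte markers were higher by a median of 2.54 with 8 of 14 passing when adjusted over the list alone (camera adjusted p of 5.16e-05), MHC class II genes by 2.43 with 6 of 9 (5.39e-05), mast cell, eosinophil and basophil markers by 2.92 with 5 of 8 (9.03e-05) and type I interferon genes by 1.32 with 0 of 28 (1.25e-05). Lymphocyte lists were higher as well, T cell markers by 1.28 (camera adjusted p of 0.000467) and cytotoxic effectors by 3.70 (0.000164). Without TGFbi+RT replicate 3 the passing medians were 0.56 for type I interferon, 1.37 for MHC class II and 2.31 for cytotoxic effectors, and without both libraries that stood apart 0.51 for T cell markers. Adipocyte markers had 1.59 without TGFbi replicate 1 and 4.27 without RT replicate 1. BMP genes were lower by a median of -0.37 (camera adjusted p of 0.0176), with 4 members lower and 1 higher when adjusted over the list alone, among them Hey1 with a log2 fold change of -0.80 ± 0.21. The BMP list had -0.55 without TGFbi+RT replicate 3 and did not pass without Sham replicate 1 (-0.15), TGFbi replicate 2 (-0.26) or RT replicate 1 (-0.35). Each of these 7 lists had an adjusted p of 0.735 with an estimated correlation. TGFb targets had a median of -0.12, opposite in sign to their test (camera adjusted p of 0.912), and matrix genes of -0.37, also opposite (0.490). P53 targets (0.04, 0.887) and alternative end joining (0.01, 0.887, its test in the opposite direction) did not pass. For the F test of any difference among the 5 groups edgeR called 0 genes, with 1729 at an unadjusted p under 0.05, 656 by DESeq2 and 0 by limma-voom, and 1 without Sham replicate 1, TGFbi replicate 1, TGFbi+RT replicate 3 or triple replicate 2.

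**Figure D3:**
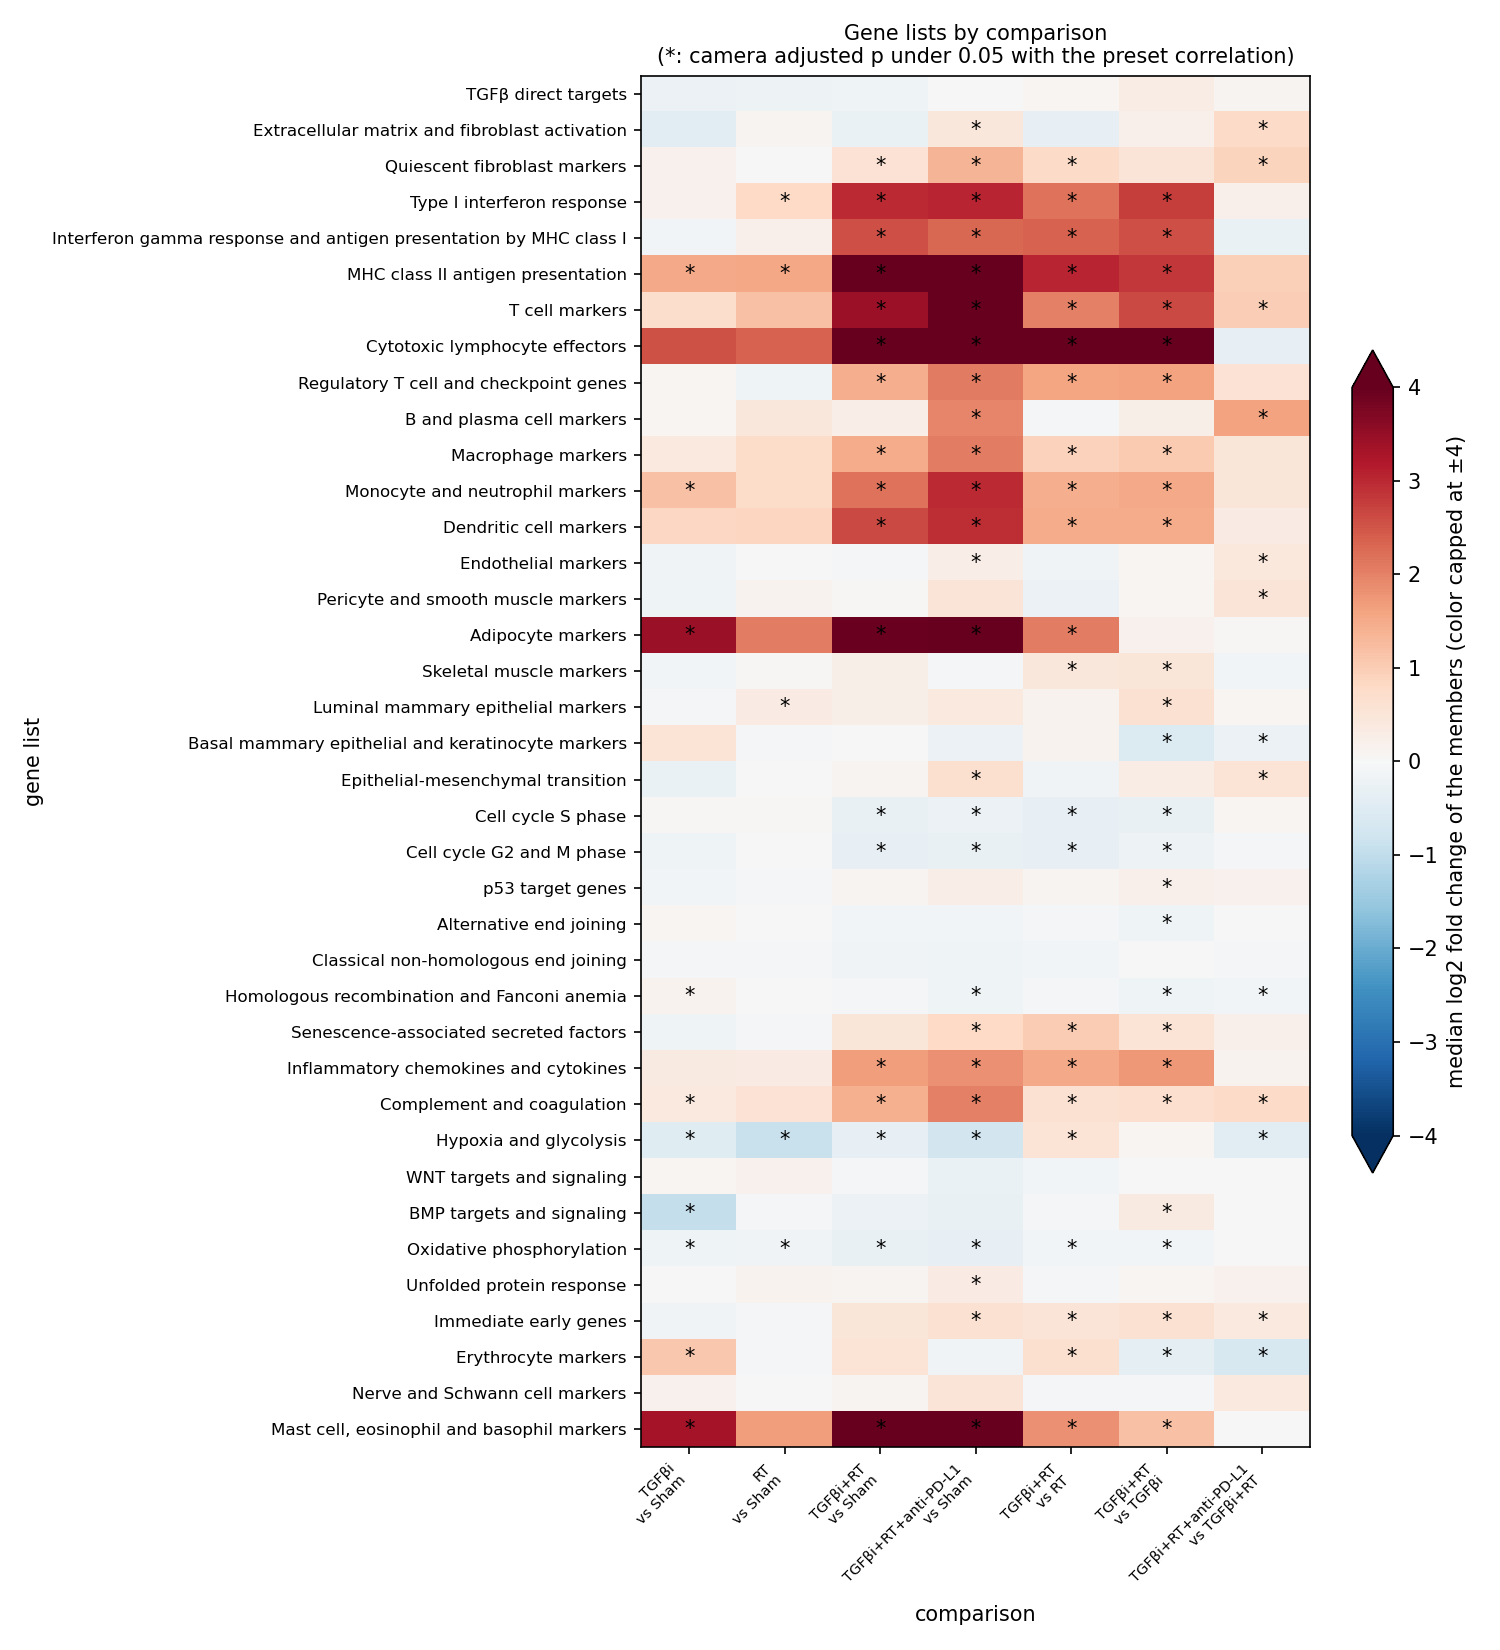
Median log2 fold change of 38 gene lists in 7 comparisons between groups, with color from lower to higher and capped at 4 in both directions, and an asterisk where the camera adjusted p was under 0.05. Hypoxia and glycolysis has a median of -0.89 in RT against Sham and 0.55 in TGFbi+RT against RT, and interferon and leukocyte lists are positive in TGFbi+RT against Sham, RT and TGFbi.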

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

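The tests of lymph node genes in triple replicate 1 and of the correlation of Trp53 with macrophage markers were set before their results were seen, and all other tests in this part, the splits of the samples included, were chosen after. Singled out here are 15 gene lists called by the test of the interaction, that is, of whether the response to radiation differed with the inhibitor. Of 60 splits of the tumors 33 called at least as many lists, and the median of the other splits was 15. The count of 15 is therefore no more than other splits give. By edgeR 608 genes had an unadjusted p under 0.05, where chance would give 801. Hypoxia and glycolysis had a median interaction of 1.00 (camera adjusted p of 1.30e-13), interferon gamma response and MHC class I 2.28 (5.66e-07), type I interferon response 1.97 (6.74e-06), regulatory T cell and checkpoint genes 1.37 (0.000532), inflammatory chemokines 1.21 (0.00199), cytotoxic effectors 1.89 (0.00224), senescence-associated secreted factors 0.69 (0.00322), BMP targets and signaling 0.60 (0.0194) and skeletal muscle markers 0.57 (0.0194). Negative were S phase genes with -0.38 (6.22e-05) and alternative end joining with -0.0711 (0.0378). Each of these 11 lists had an adjusted p of 0.799 with an estimated correlation. For the other 4 lists, immediate early genes had 0.58 (camera adjusted p of 0.0245, and adjusted p = 0.813 with an estimated correlation), TGFb direct targets 0.29 (0.0378, and adjusted p = 0.867), homologous recombination and Fanconi anemia genes -0.23 (0.0152, and adjusted p = 0.849) and G2 and M phase genes -0.17 (0.0121, and adjusted p = 0.912). The RT tumors carried another library code than the other 3 groups of this test. The list count of 15 became 1 without TGFbi+RT replicate 3, 5 without both libraries that stood apart, 24 without RT replicate 1, 8 without Sham replicate 1 or RT replicate 2, and 9 without TGFbi+RT replicate 1 or TGFbi replicate 2.

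T cell, cytotoxic and interferon lists were high in TGFbi+RT replicate 3 and triple replicate 2, with cytotoxic effectors 4.36 and 4.47 log2 units above the median of the other 13 tumors. Lymph node tissue is argued against, since the lymph node genes lay below the cytotoxic effectors in both tumors, the smaller gap being -3.54. A lower share of tumor cells is argued against as the whole cause, since the stromal lists were higher too, matrix genes by 1.08 and 1.67 and endothelial markers by 0.81 and 1.04, with macrophage markers at 2.01 and 2.55, but the highest stromal list lay below the cytotoxic effectors with a smaller gap of -2.80. The combination of TGFbi and RT stays open as a candidate explanation. The mean T cell score was 1.19 ± 1.62 in the 6 tumors given both and -0.80 ± 0.45 in the other 9 (SD, exact permutation p of 0.0024). The 6 include the 2 tumors whose high lists prompted the test, so that p is no separate support. Without the 2 tumors the permutation p was 0.0168. Without triple replicate 1 as well it was 0.0818 for T cell markers, 0.0182 for cytotoxic effectors, 0.0136 for type I interferon, 0.0364 for interferon gamma and 0.0273 for MHC class II. In the same setting the permutation p was 0.168 for macrophage markers, 0.745 for B and plasma cell markers, 0.291 for adipocyte markers and 0.364 for G2 and M phase genes. None of these values was adjusted for the number of lists, so the small ones decide little. For T cell markers within code A2301 the difference was 2.09 (4 against 6 tumors, permutation p of 0.00476). Those 4 include TGFbi+RT replicate 3, whose high score prompted the test, and triple replicate 1, so this value is no separate support.

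T and B cell lists were high in triple replicate 1, at 3.51 and 3.87 log2 units above the other 14 tumors, while cytotoxic effectors were at 0.42. A lower share of tumor cells is argued against, since the highest stromal list lay below the B cell list by a gap of -4.11. Lymph node tissue in the sample stays open as a candidate source, with a median of 3.56 for 20 lymph node genes, of which 6 are also in a fixed list and 2 reached 1 CPM in Sham. Glycam1, a product of high endothelial venules, had 28.0 CPM in this tumor against at most 0.811 CPM in the 12 tumors outside these 3, and the lymph node chemokine Ccl21a 11.6 CPM against at most 0.686 CPM. An effect of anti-PD-L1 on such tissue also stays open and was not tested.

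Trp53 reads were present in all 15 tumors although the labels call them Trp53 null. Host macrophages as the main source are argued against by the slope of Trp53 on the macrophage score, -0.08 with a 95% interval from -0.18 to 0.0261, where a slope near 1 was needed. Host cells in general cannot be told apart from reads of the altered locus, since the correlation with macrophage markers was -0.409 (permutation p of 0.131), a value below 0 but within its spread, and 0.131 without the 2 tumors that stood apart. No biological explanation was tested, and the kind of null allele is not given in the sources used here.

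Regrouping the tumors of each comparison showed what other splits give. For 3 against 3 tumors the 10 splits are too few for a share under 0.05. The splits with at least as many genes as the real one, its value and the highest other were 1 (1 and 0) for TGFbi vs Sham, 10 (0 and 0) for RT vs Sham, 10 (0 and 2) for TGFbi+RT vs Sham, 10 (0 and 0) for the triple group vs Sham, for TGFbi+RT vs RT and for TGFbi+RT vs TGFbi, and 10 (0 and 1) for the triple group vs TGFbi+RT. For gene lists, in the same order, they were 7 (10 and 25), 9 (5 and 25), 4 (18 and 27), 2 (26 and 28), 3 (22 and 27), 1 (25 and 22) and 6 (13 and 27). The median number of lists in the other splits was 11, 14, 15, 18, 15, 12 and 16, in that order. Of 60 drawn splits, the real one included, 1 gave as many genes as the 5 for the average effect of TGFbi, where the highest other was 0. That share is the smallest the 60 splits can give, and 21 counts were tested in this way. The splits also did not keep the library code, which differs between the arms and leaves 0 genes when it is in the fit. Chance is therefore not excluded for that count. Nor was it for its lists, with 23 splits (19 and 29), for the lists of the interaction, with 33 (15 and 30), or for those of the average effect of RT, with 16 (21 and 30). The median of the other splits was 15 lists in each of these 3. For genes, all 60 splits gave at least the real 0 in the interaction (highest other 2) and in the average effect of RT (highest other 0). Any split gives at least 0, so real counts of 0, here and above, decide nothing about chance. For any difference among the 5 groups all 60 splits gave at least the real 0, and the highest other gave 885 genes, which points to a structure of the samples whose cause was not tested. The counts of 0 are by edgeR, and their numbers at an unadjusted p under 0.05 and by DESeq2 and limma-voom stand with each comparison above.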

How the results depend on the processing

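Alternatives chosen after the data were seen were limma-voom with quality weights, robust empirical Bayes, and the omission of 1 abundant gene named with the methods or of the 2 libraries that stood apart, TGFbi+RT replicate 3 and triple replicate 2. All others were planned. RLE size factors, no low-count filter, robust empirical Bayes and the omission of that gene moved no count of genes or lists by more than 1.5 times. Where a cause is not named below, the cause was not tested.

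DESeq2 called 116 genes in TGFbi vs Sham, 1 in RT vs Sham, 481 in TGFbi+RT vs Sham, 619 in TGFbi+RT+anti-PD-L1 vs Sham, 63 in TGFbi+RT vs RT, 3 in TGFbi+RT vs TGFbi, 1 in TGFbi+RT+anti-PD-L1 vs TGFbi+RT, 3 in the interaction of TGFbi and RT, 468 in the average effect of TGFbi and 656 in any difference among the 5 groups. With limma-voom the count was 0 in TGFbi vs Sham and 2 in the average effect of TGFbi, and with quality weights 243 in TGFbi vs Sham, 1 in TGFbi+RT+anti-PD-L1 vs Sham, 870 in the average effect of TGFbi and 21 in any difference among the 5 groups. Without the resubmitted libraries, TGFbi replicate 3 and TGFbi+RT replicate 3, it was 0 in TGFbi vs Sham and 0 in the average effect of TGFbi, fewer samples being part of that setting. With only the 2 groups in the fit it was 0 in TGFbi vs Sham.

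A block for the replicate number gave 0 genes in TGFbi vs Sham and 2 in the average effect of TGFbi, and 172 of 174 called list medians kept their call. The numbers gave little sign of pairing, since 13 of 30 pairs of libraries with the same number had a correlation above 0.1, with a mean of -0.03 against 0.02 for other pairs and a range from -0.579 to 0.671, and 6 of the 15 libraries correlated best with 1 of the same number.

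With an estimated correlation 0 lists were called in each of the 10 contrasts, TGFbi vs Sham, RT vs Sham, TGFbi+RT vs Sham, TGFbi+RT+anti-PD-L1 vs Sham, TGFbi+RT vs RT, TGFbi+RT vs TGFbi, TGFbi+RT+anti-PD-L1 vs TGFbi+RT, the interaction of TGFbi and RT, the average effect of RT and the average effect of TGFbi, and fry gave 0 in each for change in 1 direction. For change in either direction fry gave 2 lists in TGFbi vs Sham, 2 in TGFbi+RT+anti-PD-L1 vs Sham, 1 in the average effect of TGFbi and 0 in the other 7.

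The library code as a covariate gave 0 genes in the average effect of TGFbi, and 20 lists in RT vs Sham, 17 in TGFbi+RT+anti-PD-L1 vs Sham and 23 in the interaction of TGFbi and RT. It reversed 26 of 174 called lists. In RT vs Sham the medians became -1.66 for type I interferon response, -0.95 for MHC class II antigen presentation and 0.16 for oxidative phosphorylation. In TGFbi+RT+anti-PD-L1 vs Sham they became -0.96 for extracellular matrix and fibroblast activation, -0.41 for endothelial markers, -0.55 for epithelial-mesenchymal transition, 0.15 for cell cycle S phase, 0.0147 for cell cycle G2 and M phase and -0.46 for senescence-associated secreted factors, and Homologous recombination and Fanconi anemia in TGFbi+RT+anti-PD-L1 vs Sham became 0.0801. For T cell markers in TGFbi+RT vs RT the median stayed at 2.06 while the direction of the test turned. In TGFbi+RT+anti-PD-L1 vs TGFbi+RT they became -0.61 for extracellular matrix and fibroblast activation, -0.40 for quiescent fibroblast markers, -0.34 for endothelial markers, -0.78 for epithelial-mesenchymal transition, 0.11 for homologous recombination and Fanconi anemia, -0.89 for complement and coagulation and -0.33 for immediate early genes, and Basal mammary epithelial and keratinocyte markers in TGFbi+RT+anti-PD-L1 vs TGFbi+RT became -0.0837. In the average effect of RT they became -0.15 for macrophage markers, 0.17 for cell cycle S phase, 0.19 for cell cycle G2 and M phase, 0.0666 for alternative end joining, 0.10 for homologous recombination and Fanconi anemia, 0.0630 for inflammatory chemokines and cytokines and -0.10 for complement and coagulation. For the chemokine and basal lists, whose medians kept their sign, the direction of the test turned. The code separates RT from Sham and TGFbi+RT completely, so these values rest on the 3 triple tumors, and triple replicate 1 is the tumor with lymph node genes.

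Without the 2 libraries that stood apart 2 genes were called in the average effect of TGFbi and 1 in any difference among the 5 groups, and 9 lists in RT vs Sham, 11 in TGFbi+RT vs TGFbi and 5 in the interaction of TGFbi and RT. Cell cycle S phase in TGFbi+RT+anti-PD-L1 vs Sham then had a median of -0.0377 with the test turned. Over the omissions of single tumors its median ranged from -0.475 to -0.0401, the last without triple replicate 2 and with the test turned. Homologous recombination and Fanconi anemia in TGFbi+RT+anti-PD-L1 vs TGFbi+RT ranged from -0.252 to 0.0258, the last without triple replicate 2. Homologous recombination and Fanconi anemia in TGFbi vs Sham ranged from -0.00840 without Sham replicate 1 to 0.299, and TGFb direct targets in interaction of TGFbi and RT from -0.0478 without Sham replicate 1 to 0.738.

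Leaving out each tumor in turn gave 0 to 5 genes in TGFbi vs Sham, 0 to 1 in RT vs Sham, 0 to 4 in TGFbi+RT+anti-PD-L1 vs Sham, 0 to 8 in the average effect of TGFbi and 0 to 1 in any difference among the 5 groups, with 0 in the other 6. For lists the ranges were 1 to 19 in TGFbi vs Sham, 3 to 17 in RT vs Sham, 15 to 26 in TGFbi+RT vs Sham, 19 to 29 in TGFbi+RT+anti-PD-L1 vs Sham, 17 to 26 in TGFbi+RT vs RT, 15 to 24 in TGFbi+RT vs TGFbi, 6 to 23 in TGFbi+RT+anti-PD-L1 vs TGFbi+RT, 1 to 24 in the interaction of TGFbi and RT, 14 to 26 in the average effect of RT and 15 to 22 in the average effect of TGFbi. Fewer samples are part of each of these settings. Depth limits lymphocyte genes with few reads, such as Cd3e, Cd8a and Prf1 with 1, 3 and 7 counts over the 3 Sham tumors. Bcl11b, of the T cell list, had 786 counts there, so it did not follow those T cell genes. The cells its reads came from were not tested.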

Other observations

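All tests in this part were chosen after the result was seen. The internal reference library belongs to no treatment group, and its tissue is not given in the sources used here. It held 9003730 counts, with 0 counts of the epithelial genes Krt5 and Epcam, against a floor of 0.333 CPM for 3 counts, but 601 counts of the keratin Krt14 (66.8 CPM, against a tumor median of 81.3 CPM). CPM in this part are scaled to library totals without the TMM factors. It is not a matched normal sample of these tumors.

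Fgfr2, a fibroblast growth factor receptor (chromosome 7, 130162451 to 130266808), was among the most abundant transcripts in each of the 15 tumors, at 3847 to 8731 CPM, with 1 count in the reference library. Copy number gain of the whole 2 Mb around it is argued against, since its 6 neighbors had a median log2 ratio of tumors to reference of -0.41, at percentile 23.2 of 13508 windows. A gain confined to Fgfr2 would not reach these neighbors, the nearest of which, Ate1, starts at 130391493. Such a gain was not tested. Fzd7, a Wnt receptor (chromosome 1, 59482147 to 59486955), measured 3808 to 8518 CPM in the tumors and 134 CPM in the reference. Of its 24 neighbors 22 were higher in the tumors, with a median log2 ratio of 3.36 at percentile 99.7, so a copy number gain shared by these tumors may explain its level. The reference is of unknown tissue, and no DNA was measured.

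A scan of all chromosomes for stretches of neighboring genes higher in the tumors found 5, where 100 shuffles of gene order gave at most 1. They lay on chromosome 14 around Gm3636 and Gm3373 (12 of 12 genes with a log2 ratio above 1, median 3.49), chromosome 1 around Fzd7 (28 of 33, 3.44), chromosome 8 around Lamp1 and Cul4a (22 of 25, 2.78), chromosome 10 around Mdm2 and Frs2 (16 of 18, 2.71) and chromosome 1 near Edem3 (10 of 12, 2.24), against 19.9% of all 14422 genes scanned. Windows were picked for a median log2 ratio of at least 2, so high shares above 1 follow from the selection and are no separate support. Shuffling also breaks up neighbors expressed together for any other reason, so it cannot tell copy number gain from these.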
